A study of Mus musculus with 24 samples.

How the data were processed

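Gene expression was measured with Illumina bead arrays in total RNA of mouse bone marrow-derived dendritic cells. Wild-type mice, mice without the inhibitory IgG receptor FcγRIIb and mice without the FcR γ chain, the signalling subunit shared by activating Fc receptors, were compared, all on a C57Bl/6 background. Per the labels' protocols, marrow from 12 mice, 2 of each sex per strain, was kept in separate cultures with GM-CSF for 10 days, and the share of CD11c+ cells was usually over 85%. Cells of each mouse then received medium or immune complexes of 1 µg/ml ovalbumin and 50 µg/ml rabbit anti-ovalbumin IgG for 4 hours. This gives 24 arrays in 6 groups of 4 mice.

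The deposited tables hold probe intensity on a linear scale. Per the file headers 1 table is not normalized and the other is normalized. Per the submitters' processing notes BeadStudio 3.0 was used. Its background and scaling settings are not given in the sources used here. The table that is not normalized held between 205 and 361 values below 0 per array, so some background had already been subtracted from it. Entries taken below as negative controls still had medians between 18.7 and 22.8 per array, so not all background was removed. Detection p-values are absent from this table, although its header mentions them. The columns of the normalized table had means between 0.993 and 1.02, and 20504 of its 46643 probes (44%) shared their values with another probe. Among the other probes the rank correlation between the tables was at least 0.9924 on each array. The remaining deposited table was identical to the normalized table and was not used.

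The table that is not normalized was used. It held 48286 entries, of which 1643 are absent from the deposited matrix of probes. Of these, 1603 shared 1 value per array in the normalized table and were taken as negative controls, and 40 others were left out as further controls. The plan asked for neqc with detection p-values and named a fallback for a table with values below 0 and no such p-values, and the fallback was used: normexp background correction with an offset of 50, then quantile normalization and log2. Detection p was computed as the share of negative controls at or above a probe's signal. Probes with a detection p under 0.01 on at least 4 arrays were kept (13397 probes). Probe symbols were updated by Entrez identifier to the GRCm38.p6 gene table supplied for this work. Which genome or transcripts the probes were designed on is not given in the sources used here, so no coordinates are printed. Of all probes, 32794 had 1 gene symbol, 55 had several and 13794 had none. For each symbol the probe with the highest mean was used, which left 8324 genes.

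Array codes in the labels form 4 sets of 6 arrays. Sets 04 (medium) and 40 (immune complex) hold wild-type mice 1 and 2 with the 4 FcγRIIb knockout mice. Sets 83 (medium) and 74 (immune complex) hold wild-type mice 3 and 4 with the 4 γ chain knockout mice. Medium and immune complex arrays never share a set, so treatment and set cannot be separated. Knockout and wild-type arrays were compared within a set, and responses between the same pairs of sets.

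R 4.3.3 with limma 3.58.1 was used. A linear model with 8 cell means (each knockout by treatment, and wild type by treatment and set) and 16 residual degrees of freedom was fitted with lmFit and eBayes, so that all groups share 1 estimate of the spread per gene. Benjamini-Hochberg adjusted p-values under 0.05 over the 8324 genes were called, with no fold minimum. The design, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Under that rule Fcgr2b, Fcer1g, Fcgr1, Fcgr3 and Fcgr4 are always named. Treatment comparisons add the 12 largest rises and 8 largest falls past the threshold with the immune complex array on that side of the medium array in all 4 mice. Genotype comparisons add the 8 largest differences each way with every knockout array on that side of every wild-type array of the set, and response differences add the 10 largest each way. Each gene list adds up to 4 members with the largest change past the threshold, or the 2 with the smallest p where none passed. Sex-linked transcripts were left out of the named genes.

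Gene lists covering Fc receptor biology, inflammatory, interferon, metabolic and cell-cycle programmes and markers of other cell types were tested, 29 per comparison, each with members measured here. The test was camera with a preset correlation of 0.01 and with a correlation estimated from the data, adjusted over the 29 lists. In fry, PValue tests whether a list's genes move on balance in 1 direction and PValue.Mixed whether they change in either direction. Neither compares the list with other genes. Values given as ± are standard errors on the log2 scale unless SD is stated. Where a gene was not detected on any array of a side, the fold is given as "at least", computed from the lowest normalized value that still counted as detected on each array of that side. Target genes were also compared with exact permutation tests on the means per mouse, two-sided.

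The labels give a replicate number, and the same genotype and number was taken as the same mouse. This pairing was used in the rule for named genes, in the means per mouse and in the alternative with mouse as a block. The main model held no term for mouse and took the arrays of a mouse as independent. As a check, deviations from group means were correlated over genes between arrays of 1 mouse and of different mice of a strain. The correlation was higher for the same mouse than for any other in WT 2, γ chain knockout 1, 2 and 4 and FcγRIIb knockout 2, 3 and 4, and lower in the other 5. Xist read 8.69 in medium and 9.551 with immune complex in WT 3, and 9.848 and 8.429 in WT 4. The pairing is thus not settled by these values. The consensus correlation was 0.0164 with mouse as a random block and 0.727 with code set as a random block. No 2 arrays held identical values, and correlations within groups lay between 0.9413 and 0.9976.

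Alternatives were the deposited normalized table, no background correction, median scaling, no detection filter or detection on 12 arrays, every probe tested alone, no code set, code set as a random block, only the arrays compared, array weights, mouse as a block, a 2-fold minimum and leaving out each mouse. Added after the data were seen were neqc with the negative controls, knockout mice 3 and 4 alone, and wild-type mice 1 and 2 or 3 and 4 alone. The procedure was tested on simulated data with a change added to known genes. Values were drawn independently around each gene's mean with its residual spread. No effect of set or mouse was put in, so the simulation does not bear on treatment being tied to set. An added log2 change of 1 was recovered in 97% to 100% of genes in the treatment and genotype comparisons and in 46.3% to 88.1% in the response differences. For an added change of 0.5 these were 59.7% to 88.1% and 4.48% to 37.3%. The number of arrays limits the precision of each value.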

Results

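Expression was measured on 24 bead arrays of bone marrow-derived dendritic cells, 4 mice in each of 6 groups: wild type, FcγRIIb knockout and FcR γ chain knockout, each in medium or with ovalbumin-IgG immune complexes (IC) for 4 hours. The arrays fall into 4 code sets. Mean probe intensity was 399 ± 33 (SD, n = 6) in set 04 and 337 ± 36.2 in set 40, which hold the FcγRIIb knockout with wild-type mice 1 and 2. It was 555 ± 17 in set 83 and 570 ± 48.2 in set 74, which hold the γ chain knockout with wild-type mice 3 and 4. Between 19.5% and 28.1% of probes were detected per array. By set this was 22.1% to 24.7% in set 04, 19.5% to 21.1% in set 40, 25.8% to 28.1% in set 83 and 26.2% to 27.3% in set 74. Fewer probes were thus detected in set 40, so counts of arrays with detection given below are not alike between sets. Medium and IC arrays never shared a set, so an effect of the set could not be separated from the effect of IC within a genotype. Genotypes were compared within sets, with 4 knockout and 2 wild-type mice. In medium, the sex-linked gene Eif2s3y read 8.204 and 9.161 in wild-type mice 1 and 2 and 6.089 and 6.124 in mice 3 and 4. The wild-type mice of a set were thus of the same sex, while each knockout held both sexes. Sex was not in the model, so genotype and response differences are not fully separated from it. Knockout mice 3 and 4 read like the wild-type mice of their sets, so fits with them alone are matched for sex. Values after ± are standard errors of the fitted log2 change unless SD is given, and a gene passed at an adjusted p under 0.05 with limma.

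Fcer1g, which encodes the FcR γ chain, was 12.1-fold lower in γ chain knockout cells than in the other 8 mice, with mean log2 intensity 10.85 ± 0.023 against 14.45 ± 0.078 (SD; exact permutation p = 0.00202, the smallest of 495 groupings). The brightest Fcgr2b probe read 11.21 ± 0.24 in the 4 FcγRIIb knockout mice and 11.1 ± 0.16 in the other 8 mice (SD; difference 0.111, exact permutation p = 0.372), and it was 0.299 above wild-type mice 1 and 2 of the same sets (exact permutation p = 0.133). A dimmer probe read 6.309 ± 0.12 in FcγRIIb knockout mice and 6.813 ± 0.15 in the other 8 (SD; difference -0.504, exact permutation p = 0.00202), with a difference of -0.368 from wild-type mice 1 and 2 of the same sets (exact permutation p = 0.0667, the smallest of 15 groupings). That probe was detected on 5 arrays, all of γ chain knockout cells, and the remaining probe on 0 arrays, so neither rose above background in FcγRIIb knockout cells or in wild-type mice 1 and 2. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the brightest probe, used throughout, does not show whether the gene was lost.

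**Figure D1:**
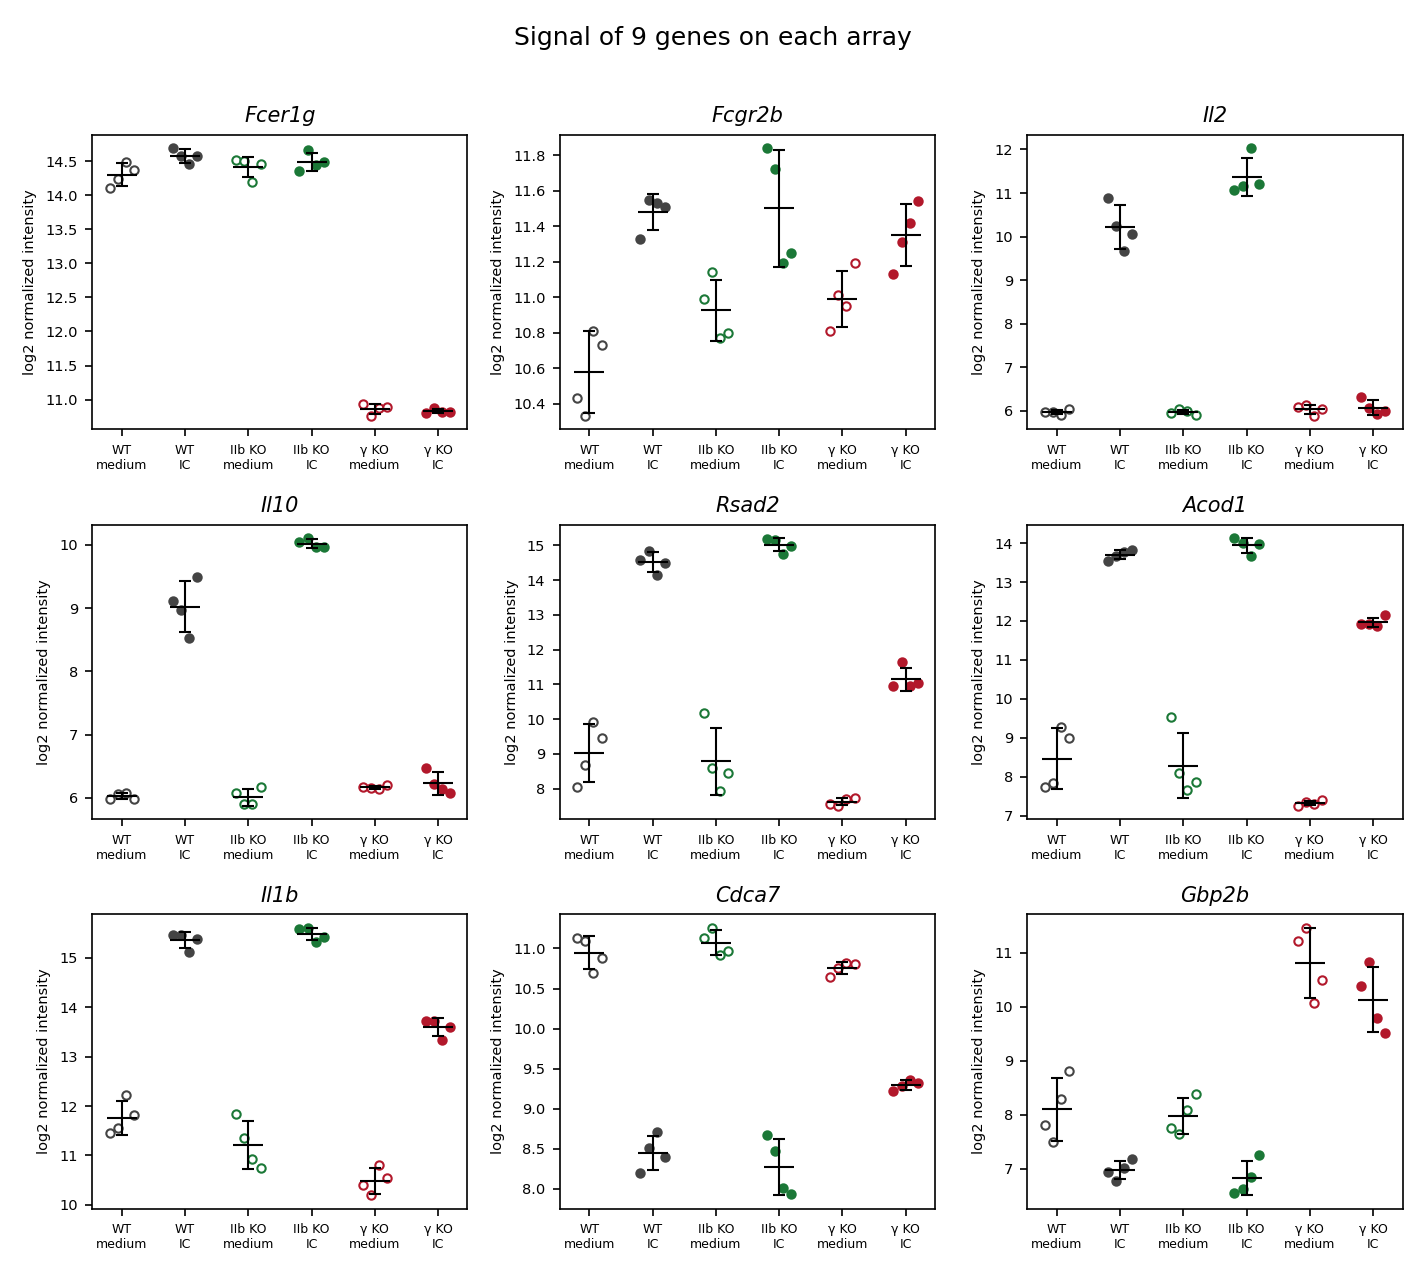
Log2 normalized intensity of 9 genes on each array, with open circles for medium and filled circles for immune complex, in wild type (grey), FcγRIIb knockout (green) and γ chain knockout (red); bars are means and whiskers SD, n = 4 mice. Fcer1g was 12.1-fold lower in the γ chain knockout, and Il2 and Il10 stayed undetected there with immune complex.

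The first comparison asked how wild-type dendritic cells respond to immune complexes. The largest rises included interferon-stimulated, interleukin and chemokine genes, along with genes of other kinds. Rsad2, an antiviral interferon-stimulated gene, rose 45.1-fold (log2 change 5.50 ± 0.287, n = 4 mice), and Acod1, the itaconate-forming enzyme of activated myeloid cells, rose 37.8-fold (5.24 ± 0.232). The T cell growth factor gene Il2 and the chemokine gene Ccl1 were detected on no medium array and rose at least 8.49-fold and at least 24.3-fold. Il10, an anti-inflammatory cytokine, rose at least 3.71-fold on the same grounds, and Cxcl10, a chemokine that attracts T cells, at least 7.92-fold. Other rises by log2 change were Ifit2 4.88 ± 0.191, Isg15 4.64 ± 0.283, Cd70, a costimulatory ligand, 4.10 ± 0.14, and Clec4e, a receptor for microbial glycolipids, 3.99 ± 0.183. Il1a (5.14 ± 0.176), Oasl1 (4.87 ± 0.184) and Cmpk2 (4.46 ± 0.16) were detected on 2 of 4 medium arrays each and Cxcl2 (4.61 ± 0.121) on 3.

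The largest falls in wild-type cells were in Psmc1, a proteasome ATPase detected on no IC array (at least 3.85-fold lower), Itpripl1 (-2.62 ± 0.123), Cdca7, a gene linked to cell division (-2.50 ± 0.125), and Dmwd (-2.49 ± 0.115). Rasl12 (-2.65 ± 0.139) and Fam78a (-2.64 ± 0.144) were detected on 3 of 4 IC arrays, Smco3 (-2.60 ± 0.171) and Rpp25 (-2.50 ± 0.0851) on 2. Among Fc receptors, Fcgr2b rose by a log2 change of 0.90 ± 0.127 and Fcer1g by 0.27 ± 0.0801, while Fcgr3, an activating receptor, fell (-0.64 ± 0.123). Fcgr1 (-0.25 ± 0.124, adjusted p = 0.0819) and Fcgr4 (0.24 ± 0.127, adjusted p = 0.1) did not pass.

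Most inflammatory lists rose in wild-type cells. In the type I interferon list, 34 of 35 measured members rose and 1 did not pass (median log2 change 2.07; adjusted p = 0.029 with an estimated correlation), and 35 rose adjusted over the list alone. All 18 chemokines rose (median 1.66; p = 0.029 with an estimated correlation), among them Cxcl1 (3.54 ± 0.229) and Ccl22 (3.32 ± 0.132). Of 24 cytokines 20 rose, 1 fell and 3 did not pass (median 1.94; 0.0057 with an estimated correlation), with Il1b at 3.60 ± 0.17 and Tnf at 3.33 ± 0.119. Among 29 genes of the NF-kB pathway, the main inflammatory transcription factor, 26 rose, led by Nfkbiz (3.10 ± 0.0974) and Tnfaip3 (2.44 ± 0.107), and 3 did not pass (0.0069). Of 33 dendritic cell maturation genes, 31 rose, such as Cd40 (3.82 ± 0.146) and Stat5a (3.41 ± 0.157), and 2 did not pass (0.012). Cell cycle genes went down, 22 of 26, with 1 rising and 3 not passing (median -1.15; 0.01), for example Tk1 (-1.96 ± 0.124) and Mcm6 (-1.61 ± 0.106).

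Other lists rose in wild-type cells too. Of 15 NRF2 targets, which respond to oxidative stress, 13 rose and 2 did not pass (median 0.874; adjusted p = 0.015 with an estimated correlation), led by Slc7a11 (2.70 ± 0.163) and Hmox1 (2.22 ± 0.127). Of 31 immediate early genes 20 rose, 4 fell and 7 did not pass (0.0099), with Atf3 at 2.10 ± 0.123. Of 24 negative feedback regulators 17 rose, 5 fell and 2 did not pass (0.01), with Il1rn, the interleukin 1 receptor antagonist, at 2.74 ± 0.156. Among 22 Toll-like receptors and adaptors 16 rose, 4 fell and 2 did not pass (0.033), with Cd14 at 2.83 ± 0.11 and Tlr2 at 2.05 ± 0.115. For MHC class I presentation 12 of 20 rose, 2 fell and 6 did not pass (0.044), led by Nlrc5 (2.73 ± 0.119) and Tap1 (1.56 ± 0.137). MHC class II presentation went both ways, with 5 of 16 rising, 6 falling and 5 not passing (adjusted p = 0.98 with an estimated correlation). Its median was 0.0611 and its mean -0.048, and the sign of the median changed with the scaling. H2-DMa, which loads peptides on class II, fell (-1.19 ± 0.103).

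In all, 5110 of 8324 genes passed in wild-type cells, 2081 up and 3029 down, and 845 changed at least 2-fold (439 up, 406 down). The share that rose was 40.7%, or 30.2% with median scaling, and with code set as a random block 1462 genes passed. Of 13 lists called by camera with the preset correlation, 11 held with the estimated one. Among 1036 genes with at least 2 called probes, 53 (5.12%) had probes called in opposite directions.

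**Figure D2:**
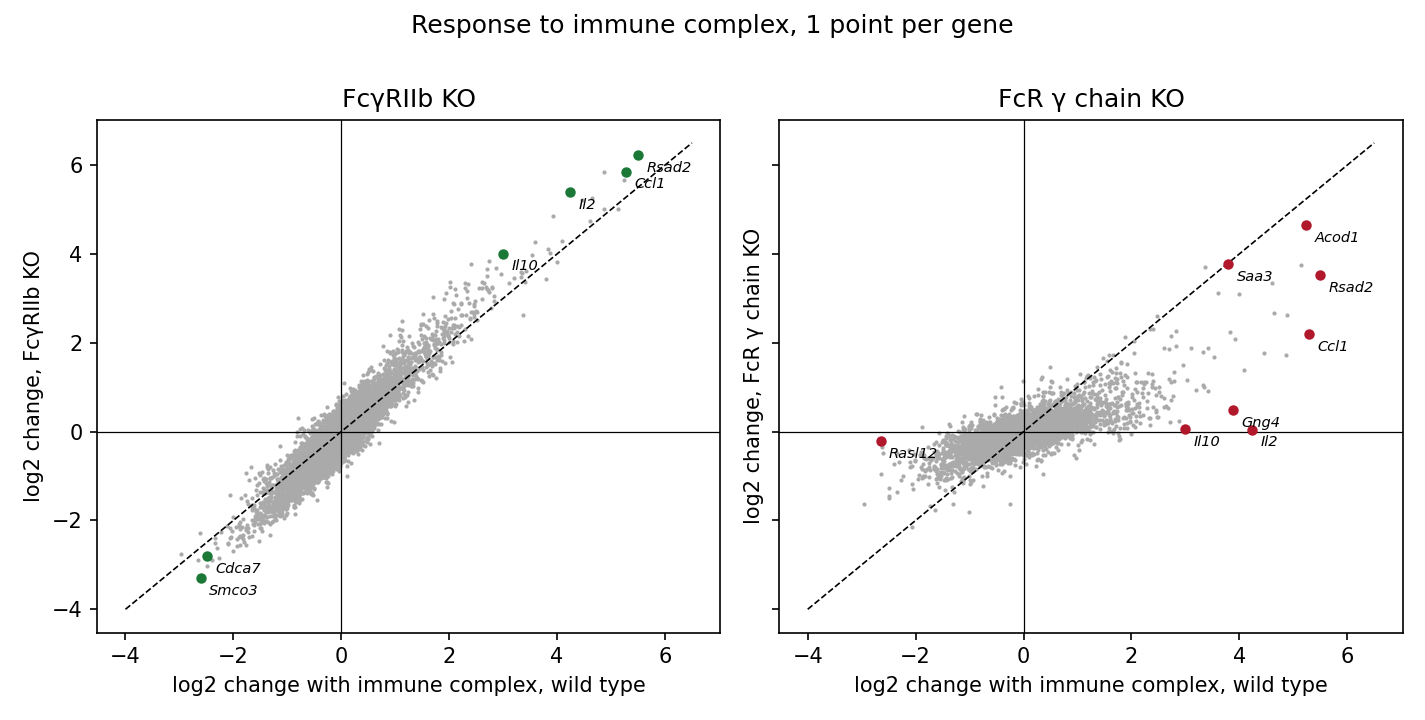
Log2 change with immune complex per gene in wild-type cells (horizontal) against FcγRIIb knockout (left) and γ chain knockout cells (right); the dashed line marks equal change and named genes are written out. Il2 and Il10 lie above the line on the left and near 0 on the vertical axis on the right. Wild-type changes average the mice of all sets, while each knockout lies in only some sets. The line thus does not compare genotypes within sets.

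The second comparison gave the IC response of FcγRIIb knockout cells. Several of the same genes were among the largest rises. The wild-type changes above average the mice of all sets, so sizes given for each knockout are not compared with them within sets. Rsad2 rose 75-fold (log2 change 6.23 ± 0.287, n = 4 mice), Acod1 50.5-fold (5.66 ± 0.232) and Isg15 38.1-fold (5.25 ± 0.283). Undetected in medium, Ccl1 rose at least 30.1-fold, Il1a at least 21.1-fold, Il2 at least 16.9-fold, Cxcl10 at least 13.6-fold and Il10 at least 6.66-fold. Ifit2 (5.01 ± 0.191), Cxcl2 (4.75 ± 0.121) and Cd70 (4.29 ± 0.14) followed, with Oasl1 (5.84 ± 0.184) detected on 1 and Cmpk2 (5.22 ± 0.16) on 2 of 4 medium arrays. Fam78a, Smco3, Rasl12 and Rpp25 were detected on no IC array and were at least 6.83-fold, 6.04-fold, 5.86-fold and 3.28-fold lower. Dmwd (-3.02 ± 0.115), Gapt (-2.89 ± 0.0916) and Cdca7 (-2.80 ± 0.125) fell, as did E2f2, a cell-cycle transcription factor (-2.85 ± 0.199, detected on 1 of 4 IC arrays).

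In FcγRIIb knockout cells all 35 interferon genes and all 18 chemokines rose (medians 2.88 and 1.89; adjusted p = 0.025 with an estimated correlation for each). Cytokines rose in 21 of 24, with 1 falling and 2 not passing (median 2.32; 0.0034), among them Il1b (4.27 ± 0.17) and Il1rn (3.84 ± 0.156). NF-kB genes rose in 26 of 29 with 3 not passing (0.0095; 27 rose adjusted over the list alone), and maturation genes in 27 of 33 with 6 not passing (0.019). Cell cycle genes fell in 24 of 26, with 1 rising and 1 not passing (median -1.38; 0.016), for example Aurkb (-2.04 ± 0.121). NRF2 targets rose in 12 of 15 with 3 not passing (0.02), and MHC class I genes in 17 of 20 with 1 falling and 2 not passing (0.015). Immediate early genes (18 of 31 up, 7 down, 6 not passing; 0.011), feedback regulators (17 of 24 up, 5 down, 2 not passing; 0.011) and Toll-like receptors (16 of 22 up, 4 down, 2 not passing; 0.02) rose as lists. For MHC class II 3 of 16 rose, 6 fell and 7 did not pass (adjusted p = 0.91 with an estimated correlation).

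Fcgr3 fell here as well (-0.66 ± 0.123). The brightest Fcgr2b probe rose by 0.57 ± 0.127 and Fcgr4 by 0.52 ± 0.127, but with median scaling they were at -0.0547 and -0.19, and the Fcgr2b probes disagreed, the dimmer one being undetected on these arrays. Fcer1g (0.07 ± 0.0801, adjusted p = 0.419) and Fcgr1 (-0.06 ± 0.124, adjusted p = 0.686) did not pass. In all 6048 genes passed, 2229 up and 3819 down, and 1324 changed at least 2-fold (561 up, 763 down). The median of all genes was -0.17, or -0.62 with median scaling, which lowered the share that rose from 36.9% to 10.7%. With code set as a random block 1861 genes passed, and 177 of 1311 genes with at least 2 called probes (13.5%) had them called in opposite directions.

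The third comparison asked what remained of the response without the FcR γ chain. Acod1 still rose 25-fold (log2 change 4.64 ± 0.232, n = 4 mice), Saa3, an acute phase gene, 13.7-fold (3.77 ± 0.236), Cd207 13.1-fold (3.71 ± 0.232) and Rsad2 11.5-fold (3.52 ± 0.287). Il1a, undetected in medium, rose at least 11.7-fold. Il1b (3.11 ± 0.17), Clec4e (3.10 ± 0.183), Isg15 (2.68 ± 0.283), Ifit2 (2.63 ± 0.191), the metalloproteinase gene Mmp14 (2.61 ± 0.271) and Tnfaip2 (2.32 ± 0.109) rose, as did Cxcl2 (3.34 ± 0.121, detected on 2 of 4 medium arrays). Il2 and Il10 were detected on none of the 8 arrays, with log2 changes of 0.0401 (adjusted p = 0.89) and 0.0606 (adjusted p = 0.79); they were picked here because they rose in the other genotypes. Falls were led by Iqgap2 (-2.15 ± 0.257), Slco2b1 (-1.81 ± 0.133), Cyp2s1 (-1.76 ± 0.138), Rnf150 (-1.68 ± 0.112), Pop4 (-1.64 ± 0.412), Arhgef18 (-1.63 ± 0.174) and Rpp25 (-1.50 ± 0.0851). Psmc1 (-1.63 ± 0.522) was detected on 3 of 4 medium arrays and 1 of 4 IC arrays.

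As lists in γ chain knockout cells, NF-kB genes rose in 24 of 29 with 5 not passing (median 0.974; adjusted p = 0.0014 with an estimated correlation), with Nfkbiz at 1.88 ± 0.0974 and Tnip1 at 1.67 ± 0.103. Chemokines rose in 16 of 18 with 2 not passing (median 1.15; 0.013), among them Ccl17 (2.05 ± 0.121), and Cxcl10, undetected in medium, rose at least 2.30-fold. Interferon genes rose in 28 of 35 with 7 not passing (median 0.781; 0.044). Of 24 cytokines 10 rose, 2 fell and 12 did not pass (median 0.26; 0.03), with 12 rising adjusted over the list alone and Tnf at 1.78 ± 0.119. Maturation genes rose in 18 of 33 with 15 not passing (0.022), for example Cd40 (2.24 ± 0.146). Cell cycle genes fell in 22 of 26 with 4 not passing (median -0.461; 0.0052), such as Mcm2 (-1.03 ± 0.118). NRF2 targets (8 of 15 up, 7 not passing; 0.022) and feedback regulators (13 of 24 up, 3 down, 8 not passing; 0.013) rose. MHC class I genes (9 of 20 up, 1 down), Toll-like receptors (9 of 22 up, 2 down) and immediate early genes (10 of 31 up, 4 down) were called with the preset correlation, and had adjusted p = 0.053, 0.053 and 0.054 with an estimated correlation. For MHC class II 3 of 16 rose, 2 fell and 11 did not pass.

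Fcgr2b rose by 0.36 ± 0.127 (adjusted p = 0.0383), while Fcgr3 (-0.47 ± 0.123) and Fcgr4 (-0.47 ± 0.127) fell. Fcer1g (-0.03 ± 0.0801, adjusted p = 0.811) and Fcgr1 (0.23 ± 0.124, adjusted p = 0.192) did not pass. In all 2086 genes passed, 829 up and 1257 down, and 159 changed at least 2-fold (112 up, 47 down). The count was 149 with code set as a random block, 1124 without the code set term, 1370 without γ chain knockout mouse 2, 3855 from these arrays alone and 4100 with array weights. The share that rose was 39.7%, or 24.9% with median scaling.

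**Figure D3:**
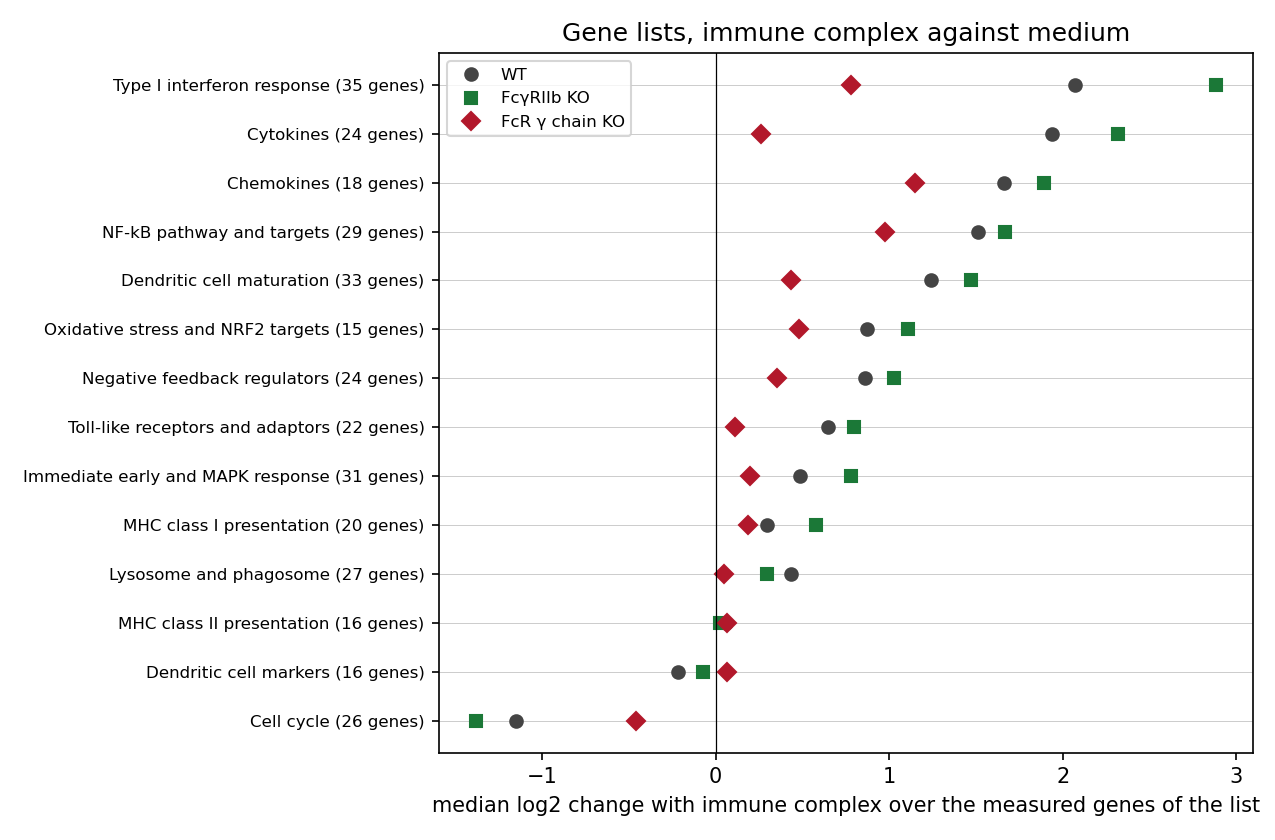
Median log2 change with immune complex over the measured genes of 14 lists in wild-type, FcγRIIb knockout and γ chain knockout cells, 4 mice each. The cytokine median is 1.94, 2.32 and 0.26 in that order, and the NF-kB median 1.51, 1.67 and 0.974. Wild-type medians average the mice of all sets, while each knockout lies in only some sets. The genotypes are thus not matched by set in this figure.

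The next comparison asked what loss of the γ chain changed in the response, by the difference of its response from that of wild-type mice 3 and 4. It was -2.26 ± 0.242 for Cd70, -2.23 ± 0.277 for Cmpk2, -2.20 ± 0.242 for Plat, a plasminogen activator, and -2.09 ± 0.175 for Tnfsf9. Il2, Il10, Gng4, Ccl1, Oasl1 and Dusp14 also passed with a lower response. No size is given for them, since none was detected in γ chain knockout cells in medium, Il2 and Il10 not with IC either, and wild-type mice 3 and 4 in medium detected Gng4 on 1 of 2 arrays and Il2, Il10 and Ccl1 on 0. Genes that fell less or rose more in the knockout were led by Rasl12 (2.19 ± 0.241), Itpripl1 (1.92 ± 0.213), the mitochondrial gene ND5 (1.81 ± 0.429), Asb2 (1.80 ± 0.175), Cebpa, a myeloid transcription factor (1.77 ± 0.272), Tspan18 (1.69 ± 0.282), Smco3 (1.67 ± 0.297), Fezf2 (1.67 ± 0.262), Dok2, an adaptor that dampens kinase signalling (1.63 ± 0.153), and Kit (1.61 ± 0.223). Fcgr1 had a higher response (0.79 ± 0.215, adjusted p = 0.0113), and Fcgr2b, Fcer1g, Fcgr3 and Fcgr4 did not pass. With IC, Fcgr1 went from 10.15 and 10.26 to 9.624 and 9.654 in wild-type mice 3 and 4. In wild-type mice 1 and 2 on other arrays Fcgr1 went from 10.6 and 10.27 to 10.54 and 10.45.

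The response of 16 of 24 cytokines was lower in γ chain knockout than in wild-type cells, with 0 higher and 8 not passing (median difference -0.926; adjusted p = 0.011 with an estimated correlation). Over the 13 cytokines detected on at least 1 array of each group compared the median was -0.274, so its size rests in part on genes under detection. Among those are Il23a and Il6, undetected in medium, with IC detected on 0 and 3 of 4 knockout arrays. Immediate early genes were lower in 9 of 31, higher in 1 and not past the threshold in 21 (0.029), for example Plk2 (-1.54 ± 0.173) and Dusp2, which among these groups only wild-type cells with IC had detected. Interferon genes were lower in 23 of 35 with 12 not passing, and in 28 adjusted over the list alone (median -1.03; adjusted p = 0.12 with an estimated correlation), among them Ifit2 (-1.99 ± 0.331). Maturation genes were lower in 16 of 33, higher in 2 and not passing in 15 (adjusted p = 0.12 with an estimated correlation). Feedback regulators (10 of 24 lower, 2 higher) and cell cycle genes (12 of 26 higher, 1 lower, such as Birc5 at 1.22 ± 0.121) both had p = 0.051 with an estimated correlation. Chemokines were lower in 5 of 18, higher in 1 and not passing in 12 (adjusted p = 0.7 with an estimated correlation), and NF-kB genes lower in 9 of 29, higher in 1 and not passing in 19 (0.35). NRF2 targets (5 of 15 lower; p = 0.26) and Toll-like receptors (6 of 22 lower; p = 0.35) were likewise called with the preset correlation alone. The response difference subtracts the difference in medium, where the knockout was already lower, with medians of -0.824 for chemokines and -0.403 for NF-kB genes. Chemokine means in medium were 10.89 and 10.56 in wild-type mice 3 and 4, and 10.14 and 10.21 in mice 1 and 2 on other arrays. A small response difference in these 2 lists thus does not show that they were independent of the γ chain.

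In all 1604 genes passed, 812 higher and 792 lower, and 269 differed at least 2-fold (81 higher, 188 lower). Without wild-type mouse 3 the count was 618, and from the arrays of these mice alone 2976. The median of all genes was 0.043, or -0.07 with median scaling, which moved the share that was higher from 50.6% to 26.1%.

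In medium, γ chain knockout cells differed from wild-type mice 3 and 4 first in Fcer1g, which was 11.9-fold lower (log2 difference -3.57 ± 0.0981, n = 4 knockout and 2 wild-type mice). Interferon and inflammatory genes were lower: Isg15 (-2.07 ± 0.346), Rsad2 (-2.06 ± 0.352), Saa3 (-1.92 ± 0.289), Acod1 (-1.81 ± 0.285), Mmp14 (-1.69 ± 0.332), Oas1g (-1.55 ± 0.235) and Il1b (-1.53 ± 0.208). Higher were Gbp2b, a guanylate-binding protein gene (2.26 ± 0.328), the lectin genes Cd209a (1.70 ± 0.202) and Cd209c (1.20 ± 0.206), Fcrls (1.33 ± 0.157), Slco2b1 (1.29 ± 0.163), Il18r1 (1.27 ± 0.205), Tspan8 (1.27 ± 0.152) and Klk1b11 (1.19 ± 0.26). Fcgr2b (0.22 ± 0.156, adjusted p = 0.392), Fcgr1, Fcgr3 and Fcgr4 did not pass.

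Among the lists in medium, chemokines were lower in 13 of 18 with 5 not passing (median -0.824; adjusted p = 0.029 with an estimated correlation), led by Ccl7 (-1.49 ± 0.233) and Ccl2 (-1.42 ± 0.263). Maturation genes (19 of 33 lower, 1 higher, 13 not passing), NF-kB genes (14 of 29 lower, 15 not passing), MHC class I genes (7 of 20 lower, 13 not passing) and immediate early genes (10 of 31 lower, 21 not passing) had p = 0.029 with an estimated correlation too, with Fscn1 at -1.25 ± 0.241, Traf1 at -1.15 ± 0.158, H2-Q7 at -0.71 ± 0.143 and Junb at -0.87 ± 0.199. Interferon genes were lower in 24 of 35, higher in 1 and not passing in 10 (median -0.567; adjusted p = 0.097 with an estimated correlation), and 28 were lower adjusted over the list alone. Cytokines were lower in 6 of 24, higher in 2 and not passing in 16 (adjusted p = 0.18 with an estimated correlation). Neutrophil precursor markers were lower in 4 of 14 with 10 not passing (adjusted p = 0.26 with an estimated correlation), with Mpo at -1.25 ± 0.345 and Elane at -0.98 ± 0.242, which stands beside these inflammatory differences. Of 13 macrophage markers 5 were higher and 8 did not pass (adjusted p = 0.45 with an estimated correlation), including the complement genes C1qc (1.07 ± 0.207) and C1qb (0.89 ± 0.159).

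In all 898 genes passed in medium, 439 higher and 459 lower, and 58 differed at least 2-fold (12 higher, 46 lower). Without wild-type mouse 3 the count was 6, although Rsad2 was still at -1.84 (adjusted p = 0.104) and Acod1 at -1.68 (adjusted p = 0.0896). Without γ chain knockout mouse 1 or 2 it was 506 or 499, with knockout mice 3 and 4 alone 374, and from these arrays alone 1768. Median scaling moved the median of all genes from 0.021 to 0.16 and the share that was higher from 48.9% to 80.9% of 1444 genes.

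With IC, γ chain knockout cells again had less Fcer1g than wild-type mice 3 and 4 (12.8-fold lower, log2 difference -3.68 ± 0.0981). Il2 was at least 7.48-fold and Il10 at least 4.14-fold lower. Gng4 (-3.36 ± 0.109), Oasl1 (-3.32 ± 0.225), Isg15 (-3.30 ± 0.346), Rsad2 (-3.18 ± 0.352), Cmpk2 (-2.97 ± 0.196) and Ifit2 (-2.92 ± 0.234) were lower. Gbp2b (3.04 ± 0.328), Rasl12 (2.95 ± 0.17), Smco3 (2.27 ± 0.21), Fcrls (2.20 ± 0.157), Asb2 (2.17 ± 0.124) and Itpripl1 (2.12 ± 0.151) were higher, as were Cd209a (2.18 ± 0.202, detected on 1 of 2 wild-type arrays) and Esyt3, at least 4.06-fold. Fcgr1 (1.16 ± 0.152) and Fcgr3 (0.57 ± 0.151) were higher and Fcgr4 (-0.48 ± 0.155) lower, while Fcgr2b, whose probes disagreed with the dimmer one detected on no wild-type array, did not pass (-0.17 ± 0.156, adjusted p = 0.407). Fcgr1 read 9.624 and 9.654 in wild-type mice 3 and 4, but 10.54 and 10.45 in wild-type mice 1 and 2 on other arrays. Fcgr3 read 11.82 and 11.86, but 12.29 and 12.5. These 2 differences thus rest in part on low values in wild-type mice 3 and 4.

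Interferon genes were lower with IC in 34 of 35 and higher in 1 (median -1.76; adjusted p = 0.036 with an estimated correlation). Cytokines were lower in 19 of 24, higher in 1 and not passing in 4 (median -1.41; 0.0056). Maturation genes (28 of 33 lower, 1 higher, 4 not passing; 0.017), NF-kB genes (22 of 29 lower, 7 not passing; 0.023), immediate early genes (19 of 31 lower, 4 higher, 8 not passing; 0.0056), feedback regulators (16 of 24 lower, 2 higher, 6 not passing; 0.016) and NRF2 targets (13 of 15 lower, 2 not passing; 0.038) were lower too. Examples are Cd70 (-2.75 ± 0.171), Rel (-1.47 ± 0.121), Nr4a3 (-2.08 ± 0.134), Rgs1 (-2.44 ± 0.214) and Hmox1 (-1.47 ± 0.156). Cell cycle genes were higher in 21 of 26, lower in 1 and not passing in 4 (median 0.693; 0.017), for example Tk1 (1.45 ± 0.152). Chemokines were lower in 16 of 18 with 2 not passing (median -1.16), with Ccl22 at -2.57 ± 0.161, and MHC class I genes lower in 11 of 20 and higher in 1. These 2 lists had adjusted p = 0.07 and 0.08 with an estimated correlation. MHC class II genes were higher in 9 of 16, lower in 1 and not passing in 6 (median 0.357; adjusted p = 0.38 with an estimated correlation), with H2-DMa at 1.42 ± 0.126.

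Markers of myeloid subtypes moved as well with IC. Dendritic cell markers were higher in 8 of 16, lower in 2 and not passing in 6 (adjusted p = 0.35 with an estimated correlation), with Mgl2 at 1.82 ± 0.104 and Irf8 at -1.53 ± 0.161. Of 13 macrophage markers 6 were higher, led by C1qa (2.00 ± 0.185), 3 lower and 4 not passing, with a median of -0.0647, a mean of 0.366 and adjusted p = 0.74 with an estimated correlation. Neutrophil precursor markers were lower in 5 of 14, higher in 1 and not passing in 8 (adjusted p = 0.53 with an estimated correlation), with Mpo at -1.64 ± 0.345. In all 3788 genes passed, 2175 higher and 1613 lower, and 546 differed at least 2-fold (209 higher, 337 lower).

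FcγRIIb knockout cells in medium differed little from wild-type mice 1 and 2. Brox, an endosomal sorting gene, was lower (log2 difference -0.61 ± 0.0863, n = 4 knockout and 2 wild-type mice, adjusted p = 0.00268), and it was the 1 gene that limma called of 8324, with 576 at an unadjusted p under 0.05. The brightest Fcgr2b probe read 0.54 ± 0.156 higher and did not pass (adjusted p = 0.619), and the other probes were undetected on these arrays. Fcer1g (0.24 ± 0.0981, adjusted p = 0.714), Fcgr1, Fcgr3 and Fcgr4 did not pass. The interferon list was called with the preset correlation (median 0.15, 0 of 35 genes passing), with adjusted p = 0.86 with an estimated correlation. Without wild-type mouse 2, 42 genes passed, and 0 passed with median scaling or from these arrays alone.

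With IC, FcγRIIb knockout cells had more of several cytokine transcripts than wild-type mice 1 and 2. Ifnb1, the interferon beta gene, was detected on 0 of these 2 wild-type and all 4 knockout arrays, at least 1.37-fold higher, although wild-type mice 3 and 4 detected it with IC. Edn1, encoding endothelin (1.20 ± 0.224), Timp1, a protease inhibitor (1.13 ± 0.136), Osm (1.03 ± 0.155), Il10 (0.98 ± 0.16) and Cxcl10 (0.77 ± 0.143) were higher, n = 4 knockout and 2 wild-type mice. So were Wdfy1 (2.08 ± 0.449), the interferon-inducible gene Ifi208 (1.29 ± 0.177), Tmem171 (1.08 ± 0.145) and Rfc2 (1.06 ± 0.168). Lower were Slc46a3 (-1.29 ± 0.198), Cd3g (-1.09 ± 0.298), Flnc, a filamin (-1.05 ± 0.207), and Ddr1 (-0.87 ± 0.217, detected on 3 of 4 knockout arrays). Chst10, Lpar3 and Grap were detected on no knockout array and were at least 1.25-fold, 1.11-fold and 1.01-fold lower, and Grwd1, also undetected there, passed as lower with no size given. Mean signal in this set was 276.9 to 336.9 on knockout arrays and 380.6 and 366.1 on wild-type arrays. Probes detected numbered 9118 to 9401 against 9621 and 9846. Whether lost detection follows this difference in signal was not tested. Fcgr2b, whose probes disagreed with the dimmer one undetected, Fcer1g, Fcgr1, Fcgr3 and Fcgr4 did not pass.

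Cytokines were higher in 10 of 24 with 14 not passing, and in 11 adjusted over the list alone (median 0.311, or 0.087 with median scaling; adjusted p = 0.057 with an estimated correlation). Interferon genes were higher in 9 of 35 with 26 not passing (median 0.311, or 0.058 with median scaling; adjusted p = 0.57 with an estimated correlation), with Zbp1 at 0.92 ± 0.245, Isg20 at 0.86 ± 0.129 and Dhx58 at 0.80 ± 0.205. Cell cycle genes were lower in 6 of 26 with 20 not passing (median -0.241, or -0.49 with median scaling; adjusted p = 0.51 with an estimated correlation), such as Bub1b (-0.51 ± 0.0889) and Cdc20 (-0.42 ± 0.099). In all 1041 genes passed, 444 higher and 597 lower, and 11 differed at least 2-fold (8 higher, 3 lower). The count was 200 without wild-type mouse 2, 450 without wild-type mouse 1, 1624 with knockout mice 3 and 4 alone, 61 from these arrays alone, and 2026 with no code set. Median scaling moved the median of all genes from -0.07 to -0.26 and the share that was higher from 42.7% to 1.57% of 3057 genes, and with the deposited normalized table that share was 25.8%.

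The response difference of FcγRIIb knockout from wild-type mice 1 and 2 asked whether loss of the inhibitory receptor changed the response. It was higher for Tnpo3 (1.06 ± 0.242), Cited2 (1.01 ± 0.189), Slc30a1, a zinc exporter (0.98 ± 0.196), and the poorly described gene A630072M18Rik (1.04 ± 0.229), and for Ifi208 (1.42 ± 0.251) and Tmem171 (1.04 ± 0.204), detected on 1 and 2 of 4 knockout arrays in medium. Ifnb1, Il10, Gm18852 and Gm4951 passed with a higher response, and no size is given for them, since these mice had none of them detected in medium. It was lower for Slc46a3 (-1.23 ± 0.28), Flnc (-1.07 ± 0.293), Pygl (-0.998 ± 0.252), Icam1, an adhesion molecule (-0.95 ± 0.201), and Gart (-0.93 ± 0.214). Chst10, Grap, Trub1, Ocrl and Lpar3 passed with a lower response, again with no size, since FcγRIIb knockout cells had none of them detected with IC, and these wild-type mice had Ocrl detected on 0 arrays. The response of Cxcl10, undetected in medium, did not pass (adjusted p = 0.0569), nor did Fcgr2b, Fcer1g, Fcgr1, Fcgr3 or Fcgr4.

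By list, cytokine responses were higher in 2 of 24 with 22 not passing, and in 6 adjusted over the list alone (median 0.336, or 0.071 with median scaling and 0.123 over the 12 detected in each of the groups compared; adjusted p = 0.19 with an estimated correlation). For the interferon list 2 of 35 were higher (median 0.154, adjusted p = 0.89 with an estimated correlation), with Isg20, detected on 2 of 4 knockout arrays in medium, at 0.92 ± 0.182, and that median was -0.14 with median scaling. In medium, FcγRIIb knockout mouse 1 had an interferon list mean of 9.283 and the other knockout mice 8.518 to 8.784. Its Rsad2 signal was 10.18, against 7.95 to 8.585 in the others. A higher level in medium lowers the fitted response of the knockout. For the cell cycle list 2 of 26 were lower (median -0.283, or -0.58 with median scaling, adjusted p = 0.48 with an estimated correlation), with Bub1b at -0.60 ± 0.126. In all 394 genes passed, 175 higher and 219 lower, and 11 differed at least 2-fold. The count was 48 without wild-type mouse 2, 64 without wild-type mouse 1, 190 without FcγRIIb knockout mouse 4, 1016 without FcγRIIb knockout mouse 1, 1085 with knockout mice 3 and 4 alone, 254 with mice paired, 168 with no code set, 62 with array weights and 0 from the arrays of these mice alone. Median scaling moved the median of all genes from -0.084 to -0.31 and the share that was higher from 44.4% to 1.42% of 1761 genes.

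**Figure D4:**
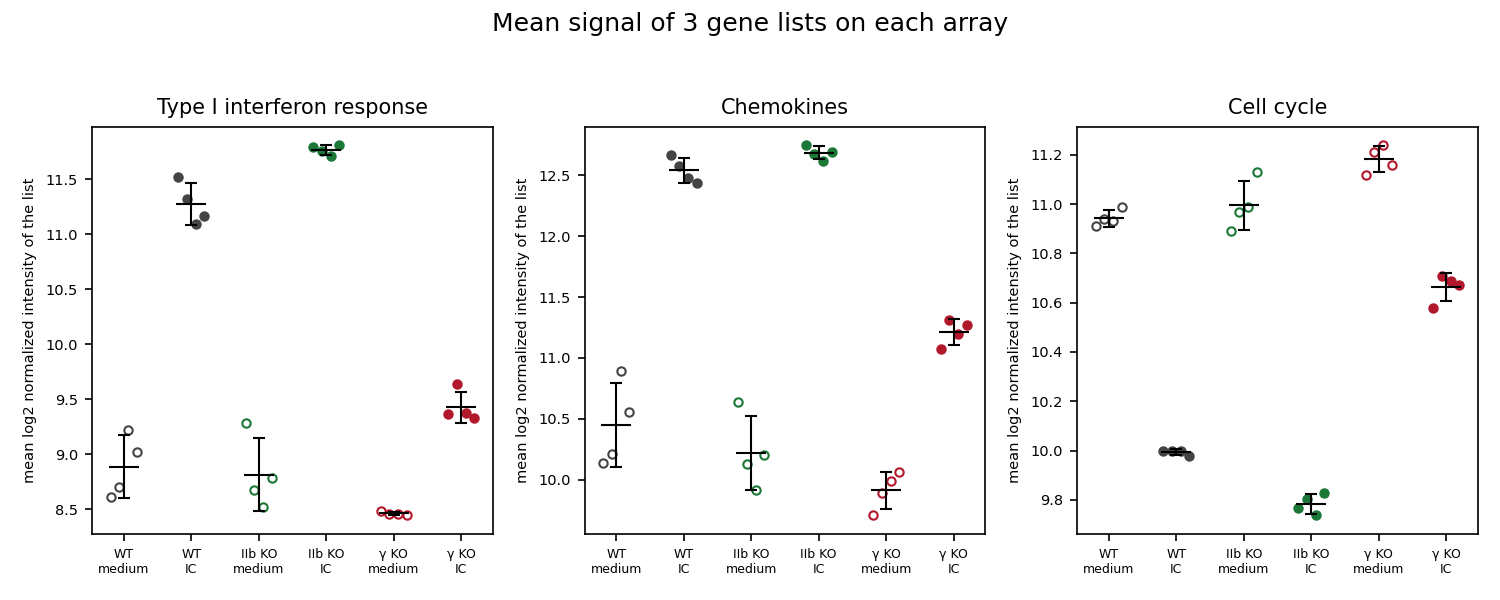
Mean log2 normalized intensity per array over the genes of the type I interferon, chemokine and cell cycle lists, by genotype and treatment, with mean and SD, n = 4 mice. In medium the interferon means of wild-type mice 3 and 4 are 9.221 and 9.02, and those of γ chain knockout mice lie between 8.453 and 8.487.

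The last comparison set the γ chain knockout response against that of the FcγRIIb knockout, each relative to the wild-type mice of its sets. Lower were Rapgef2 (-2.69 ± 0.288) and Ifi47 (-2.52 ± 0.229), and Ifi208 (-3.06 ± 0.355) and Plat (-2.72 ± 0.343), each detected on 1 of 4 FcγRIIb knockout arrays in medium. Il2, Il10, Gng4, Ccl1, Gm4951 and Cmpk2 passed as lower with no size given, since wild-type mice 1 and 2 had none of them detected in medium and γ chain knockout cells had Il2 and Il10 detected on no array. Higher were Kit (2.40 ± 0.315), Ddr1 (2.33 ± 0.434, detected on 3 of 4 FcγRIIb knockout arrays with IC), Asb2 (2.28 ± 0.248), Asgr2 (2.17 ± 0.631), Slc46a3 (2.12 ± 0.397), Dok2 (2.01 ± 0.216), Cebpa (1.99 ± 0.385) and Nfam1 (1.99 ± 0.269), as were Fezf2 and Rasl12, undetected in FcγRIIb knockout cells with IC. Cytokines were lower in 16 of 24 with 8 not passing (median -1.26, or -0.969 over the 12 detected in each of the groups compared; adjusted p = 0.0044 with an estimated correlation). Fcgr1 had a higher response (0.91 ± 0.304, adjusted p = 0.0387), and Fcgr2b, Fcer1g, Fcgr3 and Fcgr4 did not pass. Immediate early genes were lower in 10 of 31 and higher in 2, and feedback regulators lower in 9 of 24 and higher in 1 (0.036 for each). Cell cycle genes were higher in 14 of 26 and lower in 1 (median 0.699; 0.036). Interferon genes were lower in 23 of 35 with 12 not passing (adjusted p = 0.15 with an estimated correlation), and maturation genes, NF-kB genes and chemokines, called with the preset correlation, had p = 0.48, 0.61 and 0.64 with an estimated correlation.

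In all 1608 genes passed, 962 higher and 646 lower, and 652 differed at least 2-fold (307 higher, 345 lower). The count was 752 without wild-type mouse 3, 1050 without wild-type mouse 2 and 2916 with no code set. Median scaling moved the median of all genes from 0.091 to 0.2 and the share that was higher from 59.8% to 73.7%. Of the genes that rose in γ chain knockout cells, 626 also rose in FcγRIIb knockout cells on other arrays, where independent lists would share 222, and of those that fell 1078 also fell (576.7). The log2 changes of these genotypes had r = 0.679 across genes, which are not independent replicates, and those of wild-type and FcγRIIb knockout cells r = 0.933.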

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

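The tests of 1 reduced response size, of a receptor that does not use the γ chain, of 1 raised wild-type mouse and of loss of the γ chain were chosen only after the results were seen, while the tests of code sets, sex and sample splits were planned.

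The first pattern weighed is the IC response that remained without the FcR γ chain. A difference between the code sets of medium and IC arrays would not be shared by other arrays, yet 89.5% of the genes called in γ chain knockout cells moved the same way in FcγRIIb knockout cells on the other pair of sets, against 65.8% of the genes not called, although an effect common to both IC sets stays open. A response reduced by 1 factor for all genes stays undecided. Of the 1324 genes changed at least 2-fold in FcγRIIb knockout cells, 28.9% differed from the fitted 31.2% of that response, above the 25% set for excluding it, but against wild-type mice 3 and 4, a reference added after the values were seen, 19.3% differed from a fitted 45.4%. Signal through a receptor that does not use the γ chain also stays open. Of genes that rose at least 2-fold in FcγRIIb knockout cells, 35 NF-kB and chemokine genes kept a median of 57.3% of that response. The 19 cytokine genes kept 14.3%. The permutation p = 1e-05 is the smallest that 100000 permutations can give, but it takes genes as independent, some of them under detection. The lists were also picked after their shares were seen, so this p does not decide.

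By list, shares were taken over members that rose at least 2-fold in FcγRIIb knockout cells. For Toll-like receptors and adaptors these were 8 of 22 genes, with a median share of 72% and single genes between 0.124% and 112%. Over all 22 the median log2 change was 0.795 in FcγRIIb and 0.111 in γ chain knockout cells. The median share kept was 58.1% for NF-kB genes, 56.4% for chemokines, 32.2% for maturation genes, 29.7% for interferon genes and 14.3% for cytokines. Single cytokines lay between -3.65% and 74.8%. Over the 8 cytokines detected on at least 1 array of both knockouts in medium and with IC the median was 32.1%, so the low cytokine share rests in part on genes under detection, while it was 58.1% for 19 NF-kB genes and 57.1% for 14 chemokines detected so. By gene, picked after the values were seen, γ chain knockout cells kept 82.1% of the FcγRIIb knockout log2 response of Acod1, 72.8% for Il1b, 70.3% for Cxcl2, detected on 2 of their 4 medium arrays, and 112% for Tnfaip2. They kept 56.5% for Rsad2, 32.2% for Cd70 and -2.38% for Tnfsf9, detected on 3 of 4 FcγRIIb knockout arrays in medium. No share is given for Il1a, Cxcl10, Ccl1, Gng4, Il10 and Il2, which neither knockout had detected in medium. All these shares take the FcγRIIb knockout, on other sets, as the reference. With wild-type mice 3 and 4 of the same sets as reference, the fitted share was 45.4% rather than 31.2%. Shares by list and gene can thus depend on the reference.

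The second pattern is the lower interferon and inflammatory expression of γ chain knockout cells in medium. Raised expression in 1 wild-type mouse is argued against, since the median interferon difference was -0.559 from wild-type mouse 4 and -0.689 from mouse 3, and sex is argued against by -0.565 for knockout mice 3 and 4, whose Xist and Eif2s3y signals were like those of these wild-type mice. The interferon median was below both wild-type mice in 4 of 4 knockout mice, which restates the pattern and does not test whether loss of the γ chain caused it. A raised level in both cultures of wild-type mice 3 and 4 stays open, since their list means were 9.221 and 9.02, those of wild-type mice 1 and 2 on other arrays 8.608 and 8.703, and those of the knockout mice 8.453 to 8.487. Without wild-type mouse 3, which leaves 1 wild-type array, 6 genes were called, while the differences stayed near those reported, at -1.84 for Rsad2, -1.68 for Acod1 and -1.32 for Il1b.

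Responses were compared between genotypes by a test of the difference itself. FcγRIIb knockout and wild type differed in 394 genes, with fitted values from 1.42 for Ifi208, detected on 1 of 4 knockout arrays in medium, to -1.23 for Slc46a3. That count does not hold firmly: another split of the mice gave 977, 48 genes passed without wild-type mouse 2, and 0 from the arrays of these mice alone. The γ chain knockout and wild type differed in 1604 genes, with fitted values from 2.19 for Rasl12 to -3.85 for Il2, and the knockouts differed from each other in 1608, from 2.49 for Fezf2 to -4.65 for Il2. The values for Il2 and Fezf2 are not sizes of change, since Il2 was undetected on all medium arrays and on all γ chain knockout arrays with IC, and Fezf2 with IC in FcγRIIb knockout cells and in wild-type mice 1 and 2.

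Probes with no gene name lay outside the comparisons of genes. Of 2052 detected, 1029 were called with IC in wild-type, 1364 in FcγRIIb knockout and 403 in γ chain knockout cells, and 131, 234 and 23 of them changed at least 2-fold.

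A single array stood apart from the other 3 of its group in 7 of 84 groups tested, where chance marks about 1 in 20 groups, or 4.2. Mean signal was 543.2 for γ chain knockout mouse 3 in medium (others 568.1 to 572.7) and 477.4 for mouse 4 with IC (others 580.7 to 585.9). Fcgr2b was 11.33 in wild-type mouse 1 with IC (others 11.51 to 11.55), and Fcer1g 14.2 in FcγRIIb knockout mouse 3 in medium (others 14.46 to 14.51). The interferon list mean was 8.487 in γ chain knockout mouse 1 in medium (others 8.453 to 8.456) and 9.64 in mouse 2 with IC (others 9.329 to 9.376). The cell cycle list mean of wild-type mouse 4 with IC was 9.976.

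Other splits of the mice were counted for each comparison. For the difference between the knockout responses 1 of 35 splits, the real one, gave as many genes, 1608 against 0. That split is also the one that follows the code sets, and every other split puts mice of different sets into the same group. The mice are thus not interchangeable, so the count of splits excludes neither chance nor a difference between sets. For the IC responses too the real split was the 1 as large of 35, but these splits ignore the pairing of arrays by mouse, and the 8 that part the arrays of every mouse are too few for a share under 0.05. FcγRIIb knockout cells gave 6048 genes against at most 1899 in another split and γ chain knockout cells 2086 against 4. Wild-type cells gave 4011, fitted without the code set, against 3502 for mice 1 and 2 against mice 3 and 4, a split that follows code sets and sex-linked signal and points to a structure of the samples; with the code set in the model the real count was 5110. Among the 8 splits, the real one included, that part every mouse, the highest other was 1024 in wild-type, 1899 in FcγRIIb knockout and 0 in γ chain knockout cells, and the remaining splits keep some pairs of a mouse together.

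The comparisons with 2 wild-type mice have 15 splits, too few for a share under 0.05. The γ chain knockout gave 898 genes in medium (highest other 2), 3788 with IC (1) and 1604 for the response (0), each with 1 split as large, its own. The FcγRIIb knockout gave 1 gene in medium, with 8 splits as large and a highest other of 268. It gave 1041 with IC (highest other 1207) and 394 for the response (977), each with 2 splits as large. The highest other in these 3 set FcγRIIb knockout mice 3 and 4 apart from the other mice. Knockout mice 3 and 4 have Eif2s3y signal as wild-type mice 1 and 2 do, so that split does not follow sex over all these mice. Within the knockout it does, since knockout mice 1 and 2 have Xist signal instead. A genotype difference that varies with sex and another structure of the samples both stay open.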

How the results depend on the processing

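Neqc with the negative controls, knockout mice 3 and 4 alone, and wild-type mice 1 and 2 or 3 and 4 alone were chosen after the data were seen; the other alternatives were planned.

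The counts of called genes stayed within 1.5 times the reported ones in all 10 comparisons with no background correction, detection on 12 arrays and neqc. Of 217 results for named genes, 216 kept their direction and side of the threshold with no background correction, 214 with neqc, 211 with the deposited table, 211 with no detection filter, 212 with mouse as a block, 200 with median scaling, 200 with array weights, 197 with code set as a random block and 190 with no code set. With detection on 12 arrays 205 of 205 did, with only the arrays compared 162 of 192, and with knockout mice 3 and 4 alone 135 of 142. Leaving out a wild-type mouse kept 82 of 102 without mouse 1, 74 of 102 without mouse 2 (22 weaker, 6 reversed), 99 of 115 without mouse 3 and 110 of 115 without mouse 4, and leaving out a knockout mouse kept at least 95 of 102 or 111 of 115. The wild-type IC count was 4606 from mice 1 and 2 and 3617 from mice 3 and 4.

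The cause of the following differences was not tested, except that a 2-fold minimum, fewer arrays and more probes change the counts by construction. In FcγRIIb knockout against wild type in medium, 2 genes passed with the deposited table, 0 with median scaling, 4 with no detection filter, 0 with only the arrays compared and 4 with knockout mice 3 and 4 alone. With IC the FcγRIIb knockout differed in 3057 with median scaling, 1615 of every probe tested, 2026 with no code set, 61 with only the arrays compared and 1624 with knockout mice 3 and 4 alone. Its response differed from wild type in 1761 with median scaling, 168 with no code set, 0 with only the arrays compared, 62 with array weights, 254 with mouse as a block and 1085 with knockout mice 3 and 4 alone. Its IC response was called in 9338 of every probe tested and in 1861 with code set as a random block. With mouse as a block no other count left the range of 1.5 times.

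The γ chain knockout in medium differed in 1444 with median scaling, 1768 with only the arrays compared and 374 with knockout mice 3 and 4 alone. Its IC response was called in 1124 with no code set, 149 with code set as a random block, 3855 with only the arrays compared and 4100 with array weights. Its response differed from wild type in 2976 with only the arrays compared and from the FcγRIIb knockout in 2916 with no code set. That last comparison uses all arrays, so only the arrays compared adds nothing to it. The wild-type IC response was called in 1462 with code set as a random block.

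With at least 2-fold changes the counts were 845, 1324 and 159 for IC in wild-type, FcγRIIb knockout and γ chain knockout cells, 0 and 11 for FcγRIIb knockout against wild type in medium and IC, 58 and 546 for the γ chain knockout, and 11, 269 and 652 for the response differences.

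Leaving out 1 mouse gave 4380 to 4663 genes for the wild-type, 5639 to 5970 for the FcγRIIb knockout and 1370 to 1564 for the γ chain knockout response. FcγRIIb knockout against wild type gave 1 to 42 in medium and 200 to 1533 with IC, and the γ chain knockout 6 to 962 and 2621 to 3450. The response differences gave 48 to 1016 (FcγRIIb knockout and wild type), 618 to 1301 (γ chain knockout and wild type) and 752 to 1980 (between knockouts). Without wild-type mouse 2 these were 42, 200 and 48 for the FcγRIIb knockout, and without mouse 3 they were 6, 2621 and 618 for the γ chain knockout. Where 1 wild-type mouse of a set was left, it was assumed to vary like the other groups.

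Directions reversed for Fc receptor genes, of which Fcgr2b and Fcgr4 in the FcγRIIb knockout IC response were past the threshold as reported. In wild-type cells with IC, Fcgr1 was 0.0576 from mice 1 and 2 and Fcgr4 -0.14 from mice 3 and 4. In FcγRIIb knockout cells with IC, median scaling gave Fcgr2b -0.0547, Fcer1g -0.0345 and Fcgr4 -0.19, the random block gave Fcer1g -0.0893 and array weights gave Fcgr1 0.033. The random block gave Fcer1g 0.129 in γ chain knockout cells.

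In FcγRIIb knockout against wild type in medium, Fcgr1 was -0.0129, Fcgr3 -0.0165 and Fcgr4 0.103 without wild-type mouse 2, Fcgr3 -0.00231 and Fcgr4 0.0319 without knockout mouse 4, and Fcgr4 0.00305 with array weights. Leaving out 1 mouse there gave up to 0.312 for Fcgr1 and 0.199 for Fcgr3 and down to -0.212 for Fcgr4, all without wild-type mouse 1. With IC, Fcgr2b was -0.267 with median scaling, -0.0495 without wild-type mouse 1, -0.0569 without knockout mouse 1, -0.0149 without knockout mouse 2 and -0.223 with knockout mice 3 and 4 alone. There Fcgr1 was -0.267 with median scaling, -0.0127 without wild-type mouse 2 and -0.0478 without knockout mouse 4, and Fcgr3 was 0.147 with no code set and 0.0164 without knockout mouse 3. The other ends of these ranges were 0.165 for Fcgr2b without wild-type mouse 2, 0.0927 for Fcgr1 without knockout mouse 2 and -0.241 for Fcgr3 without wild-type mouse 1.

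Fcgr4 in the γ chain knockout in medium was 0.0333 with median scaling and 0.0897 with no code set. In the response differences, FcγRIIb knockout minus wild type gave Fcgr1 0.195 and Fcgr4 0.28 with no code set, Fcgr1 0.000111 without wild-type mouse 2 (lowest -0.23 without mouse 1) and Fcgr4 0.00444 without wild-type mouse 1 (lowest -0.213 without mouse 2). The γ chain knockout minus wild type gave Fcer1g 0.00735 with the deposited table and 0.00749 without wild-type mouse 4 (lowest -0.232 without mouse 3). Between the knockouts, Fcgr2b was -0.00857 with the deposited table, -0.211 with no code set and -0.0632 without wild-type mouse 2 (highest 0.251 without mouse 1), and Fcer1g -0.106 with no code set.

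Lists called by camera with the preset correlation and with the estimated one were 13 and 11 for wild-type, 13 and 11 for FcγRIIb knockout and 12 and 8 for γ chain knockout cells with IC. They were 1 and 0 in medium and 3 and 0 with IC for FcγRIIb knockout against wild type, and 13 and 5, and 12 and 8, for the γ chain knockout. The response differences gave 3 and 0, 10 and 2, and 8 and 4. Signal over background lay between 12.4 and 30.5 per array, which limits what can be said of genes near the background.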

Other observations

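The tests of a segment of another strain and of other probes were planned before their results, while its control in treatment contrasts, its repeat without the genes that raised it, the markers singled out below and the genes on chromosome 1 were chosen after values were seen.

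Signalling and metabolic genes also moved with IC. Of 33 Fc receptor and ITAM signalling genes 13 rose and 11 fell in wild-type cells (adjusted p = 0.77 with an estimated correlation), with Blnk at 1.86 ± 0.116, Dok3 at -2.03 ± 0.119, Dok2 at -1.89 ± 0.0881 and the inositol phosphatase gene Inpp5d at -1.71 ± 0.13. In FcγRIIb knockout cells 12 rose and 13 fell, and in γ chain knockout cells 10 rose and 7 fell. The γ chain knockout response was higher than that of wild type for Dok3 (1.27 ± 0.205) and Inpp5d (1.01 ± 0.226) and lower for Blnk (-1.20 ± 0.2). Of 11 oxidase and lipid mediator genes 6 rose and 3 fell in wild-type cells, 6 and 4 in FcγRIIb knockout cells and 4 and 1 in γ chain knockout cells, with Cybb at 1.30 ± 0.102 and Alox5 at -1.31 ± 0.17 in wild type. Nos2, undetected in medium, rose at least 1.10-fold in wild-type cells, where 2 of 4 IC arrays detected it, and at least 2.29-fold in FcγRIIb knockout cells. Of 27 lysosome and phagosome genes 16 rose and 5 fell in wild-type cells (adjusted p = 0.3 with an estimated correlation), 15 and 4 in FcγRIIb knockout cells (0.31, with a median that changed sign with median scaling), and 3 and 1 in γ chain knockout cells.

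Further lists were not called by camera with IC in any genotype. Glycolysis genes rose in 7, 5 and 2 of 18 and fell in 4, 6 and 4 in wild-type, FcγRIIb knockout and γ chain knockout cells, with Slc2a6 at 1.60 ± 0.087 in wild type. Cholesterol biosynthesis genes rose in 7, 6 and 1 of 17 and fell in 5, 4 and 0, with Sqle at 0.84 ± 0.12 in wild type. Cholesterol efflux genes rose in 3, 3 and 1 of 10 and fell in 2, 3 and 2. Unfolded protein response genes rose in 8, 7 and 4 of 14 and fell in 3, 5 and 2, with Herpud1 at 1.41 ± 0.105 in wild type. The 7 measured Fc receptor genes rose in 3, 3 and 1 and fell in 2, 2 and 3, and their wild-type median of 0.244 and mean of -0.0177 differ in sign. The 34 genes of distal chromosome 1 rose in 14, 13 and 5 and fell in 11, 11 and 4.

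Genes on marker lists of other cells moved both ways. With IC in wild-type, FcγRIIb knockout and γ chain knockout cells, dendritic cell markers rose in 3, 4 and 3 of 16 and fell in 7, 7 and 2, and macrophage markers rose in 6, 4 and 3 of 13 and fell in 1, 3 and 1 (adjusted p = 0.26, 0.31 and 0.12 with an estimated correlation). Neutrophil precursor markers rose in 2, 0 and 1 of 14 and fell in 2, 4 and 0. Mast cell, basophil and eosinophil markers rose in 1, 1 and 2 of 9 and fell in 1, 2 and 0, with Hdc, which makes histamine, at 1.60 ± 0.105 in wild type. Plasmacytoid markers rose in 3, 4 and 3 of 7 and fell in 3, 3 and 0, T and NK cell markers rose in 2, 1 and 1 of 6 and fell in 4, 4 and 0, B cell markers rose in 1, 1 and 0 of 2, and stromal markers rose in 1, 0 and 0 of 3 and fell in 1, 1 and 0. Of the erythroid list Car2 alone was measured. It was lower in γ chain knockout than in wild-type cells in medium (-1.50 ± 0.236).

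In γ chain knockout cells in medium, lists called with the preset correlation and lost with the estimated one were also NRF2 targets (1 of 15 higher, 5 lower), cell cycle genes (5 of 26 higher, 0 lower) and plasmacytoid markers (1 of 7 higher, 3 lower), each with adjusted p = 0.097 with an estimated correlation. Feedback regulators (7 of 24 lower) and MHC class II genes (2 of 16 higher, 1 lower) were lost as well, with adjusted p = 0.11 and 0.26 with an estimated correlation in limma. With IC, Toll-like receptors were higher in 5 of 22 and lower in 9 (adjusted p = 0.26 with an estimated correlation).

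The third pattern weighed is that Brox, called in medium, and Wdfy1 and Ifi208, the largest rises with IC, in FcγRIIb knockout against wild-type cells, lie on chromosome 1 as Fcgr2b does. Chromosome 1 did not lead more widely: of 81 genes called with both treatments averaged, 7 were on it, where 5.22% of tested genes lie (Fisher exact p = 0.199). A segment of another strain around the targeted gene stays open: the mean absolute t of 194 genes nearest Fcgr2b lay at percentile 99.1 of runs on other chromosomes, but at 87.8 without Brox and Ifi208, and Wdfy1 lies outside that window. The same window, where no segment differs within a genotype, lay at percentile 96.1 for IC in wild-type, 83.3 in FcγRIIb knockout and 23.5 in γ chain knockout cells. The window around Fcer1g lay at 99 in γ chain knockout against wild-type cells. Fcer1g lies close to Fcgr2b, so these windows share genes. The Fcer1g window also surrounds that knockout's own targeted gene, so it is no control for a segment. A probe that reads a variant also stays open, since 0 other probes of these genes were detected.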
